A study of Mus musculus with 48 samples.

How the data were processed

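Newly made RNA was measured in mouse embryonic stem cells (ESCs) labelled with 4-thiouridine (4SU) for 30 min in cycling cells and for 15 min in synchronized cells, per the labels' protocols. RNA was extracted with Trizol LS and libraries were made with the KAPA RNA HyperPrep kit. The deposited values are whole-number counts per gene, not normalized, in 3 tables: 16 libraries of cycling FOXD3-iKO cells, 8 of cycling OCT4-tetOff cells and 24 of synchronized FOXD3-iKO cells. Reads were aligned to the mouse build mm10 with STAR and counted with featureCounts, per the submitters' processing notes. Program versions, the strand setting and the handling of reads with several matches are not given in the sources used here, so values of overlapping or antisense genes and of near-identical copies are uncertain. Each table lists 54752 genes, and in all 54752 the given length equals end less start plus 1, so introns lie inside the counted interval. 53861 of the gene IDs matched the name table with their version and 54723 without it. The counts were used as deposited. Every sample column was mapped to a sample, and the tables hold no counts of added RNA, so the planned scaling to added RNA was not run and all values are relative abundances within a library.

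Totals ran from 21827951 to 30406124 counts per library in the cycling FOXD3-iKO table, from 21113158 to 26112435 in the OCT4-tetOff table and from 7953841 to 17936504 in the synchronized table. A floor of 3 counts in a library corresponds to 0.099 to 0.137, 0.115 to 0.142 and 0.167 to 0.377 CPM (counts per 1e6 counts) in the same order. Such floors cover counting error only, because reads without molecular identifiers are not independent molecules. No pair of replicates held identical counts, and every library was kept. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

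Each of the 24 groups holds 2 libraries, taken from the sample titles. Each table was fitted as a whole with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, one mean per group, genes kept by filterByExpr with a minimum count of 10), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were treatment against solvent at each time, differences of that response between times, FOXD3 loss against OCT4 loss at 24 h in a joint fit of the 8 libraries of that time, changes over release within each arm, and one 4HT effect over all 6 release times with time as a covariate. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of the F statistic. CPM values are after TMM scaling, except those of the genes that separate all 4HT from all ethanol libraries, which are of total counts.

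33 gene lists were fixed before the data were examined, as were the contrasts, the tests, the rule for named genes and the other settings listed first below. The lists are naive pluripotency, core pluripotency, formative and primed epiblast, two-cell-like, trophectoderm, primitive endoderm, mesoderm and primitive streak, neural, germline, p53 targets, DNA replication and S phase, G2 and mitosis, DNA damage signalling and repair, immediate early, FGF and ERK response, integrated stress response, heat shock, ribosome biogenesis and MYC targets, transcription elongation and RNA polymerase II, chromatin remodelling and lysine methylation, glycolysis, cholesterol synthesis, interferon response, apoptosis regulators, autophagy and lysosome, fibroblast (feeder) markers, blood and endothelial markers, imprinted genes, WNT response, TGF-beta and nodal response, replication-dependent histones, cytosolic ribosomal proteins, and mitochondrially encoded transcripts. Each list was tested against all other genes with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01, and again with the correlation estimated from the libraries. The adjusted p-values of the lists were taken over the lists of a comparison. Members were also counted with p-values adjusted over the list alone.

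Named genes follow a fixed rule. Among called genes with an average log2 CPM of at least 1, a symbol that is not provisional, and every library of one group above every library of the other, the text names from the 12 largest changes in each direction. For the effect over all release times the group means had to differ in the same direction at all 6 times, and for time courses the largest difference from 0 h was used. For differences between responses with several times the 12 smallest p-values were used. Members of a list are named by smallest p. Foxd3 and Pou5f1 were named regardless of this rule.

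Also run, as chosen beforehand, were DESeq2 1.42.0, RLE factors, total counts alone, no low-count filter, only the compared groups, a block for the replicate number, the mean of the 6 release contrasts, leaving out each library in turn, and for lists the estimated correlation and limma's fry, which tests whether the members move at all, not whether they move more than other genes. Shared calls were tested with Fisher's exact test, one-sided. Chosen after seeing the data were scaling to total counts outside Gm26917 and Gm42418, removal of each library's trend of counts on gene length (a spline with 5 degrees of freedom entered as an offset), leaving out release 3 h, and a crossed replicate block at FOXD3 32 h and OCT4 16 h. The 4HT responses of cycling cells at 24 or 32 h and of synchronized cells averaged over the 6 release times were also compared. This joint fit of both tables was chosen after the separate results were seen. The tests were checked on simulated counts with the real means, depths and dispersions and known changes. The simulated libraries behind the rates below were drawn independently and without a gene-length trend. The real libraries had such trends, and same-numbered synchronized ones correlated, so these rates may not carry over to the data. For FOXD3 loss at 24 h, 22 of 67 genes changed 1.5-fold, 47 of 67 changed 2-fold and 58 of 66 changed 3-fold were called, with 3.8% false calls. For the effect over all release times 76.1%, 97.0% and 100.0% were called. For differences of the 4HT response between release times, simulated as changes at release 1 h alone, 0.0%, 0.0% and 43.9% were called. For OCT4 loss at 24 h 28.4%, 58.2% and 92.4% were called, with 6.3% false calls.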

Results

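Nascent RNA was sequenced from mouse ESCs after a short pulse of 4SU, a uridine analogue taken up into transcripts as they are made. The 48 libraries form 24 groups of 2. In cycling cells of an inducible FOXD3 knockout line (FOXD3-iKO), FOXD3 was depleted by 4-hydroxytamoxifen (4HT) and compared with the solvent ethanol at 8, 14, 24 and 32 h (16 libraries). In cycling OCT4-tetOff cells, doxycycline was compared with water at 16 and 24 h (8 libraries). In FOXD3-iKO cells arrested by a double thymidine block, which holds cells at the entry into DNA replication, the block was lifted 24 h after 4HT or ethanol and cells were collected at 0, 1, 2, 3, 4 and 5 h of release (24 libraries). The design asks what loss of FOXD3, a forkhead transcription factor of pluripotent cells, does to transcription, and how this compares with loss of OCT4 (Pou5f1), the POU factor that pluripotency depends on. Totals per library ran from 21827951 to 30406124 counts in the cycling FOXD3-iKO experiment, from 21113158 to 26112435 in the OCT4-tetOff experiment and from 7953841 to 17936504 in the synchronized experiment. Gm26917 and Gm42418, annotated genes that collect reads of ribosomal RNA, took 12.5 to 37.1%, 18.1 to 43% and 3.4 to 25.4% of these counts.

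The targeted genes were examined first. Foxd3 (ENSMUSG00000067261.4, mm10 chromosome 4, 99656299 to 99658622, plus strand) was lower in every 4HT library than in every ethanol library of its table. In cycling cells its level went from 9.64 ± 0.452 CPM with ethanol to 3.84 ± 1.42 with 4HT at 8 h (mean ± SD, n = 2), from 9.23 ± 1.09 to 3.34 ± 0.0406 at 24 h and from 5.97 ± 1.29 to 1.94 ± 0.72 at 32 h. The log2 fold changes were -1.33 ± 0.24 (SE) at 8 h and -1.49 ± 0.25 at 14 h, neither past the threshold over all genes (edgeR adjusted p = 0.39 and 0.14), then -1.46 ± 0.24 at 24 h (adjusted p = 0.019) and -1.63 ± 0.28 at 32 h (adjusted p = 0.0029). In synchronized cells it fell by 1.84 ± 0.14 on the log2 scale over all release times, from 5.68 ± 1.29 to 1.57 ± 0.343 CPM (n = 12, edgeR adjusted p = 7.1e-09). The part of Foxd3 that is removed is not given in the sources used here.

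Pou5f1 (ENSMUSG00000024406.16, mm10 chromosome 17, 35506018 to 35510772, plus strand) fell after doxycycline in OCT4-tetOff cells. It went from 223 ± 3.66 to 79.2 ± 0.572 CPM at 16 h, a log2 fold change of -1.50 ± 0.13 (edgeR adjusted p = 7.3e-05). At 24 h it went from 187 ± 14.7 to 52.6 ± 8.98 CPM, a change of -1.83 ± 0.13 (adjusted p = 1.1e-05, n = 2). Foxd3 itself fell after OCT4 loss, by 1.93 ± 0.17 at 16 h and by 3.12 ± 0.20 at 24 h on the log2 scale (edgeR adjusted p = 8.3e-05 and 5.6e-06). Pou5f1 did not pass the threshold after FOXD3 loss: its changes were -0.19 ± 0.13 at 24 h (adjusted p = 0.82) and -0.42 ± 0.13 at 32 h (adjusted p = 0.055).

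**Figure D1:**
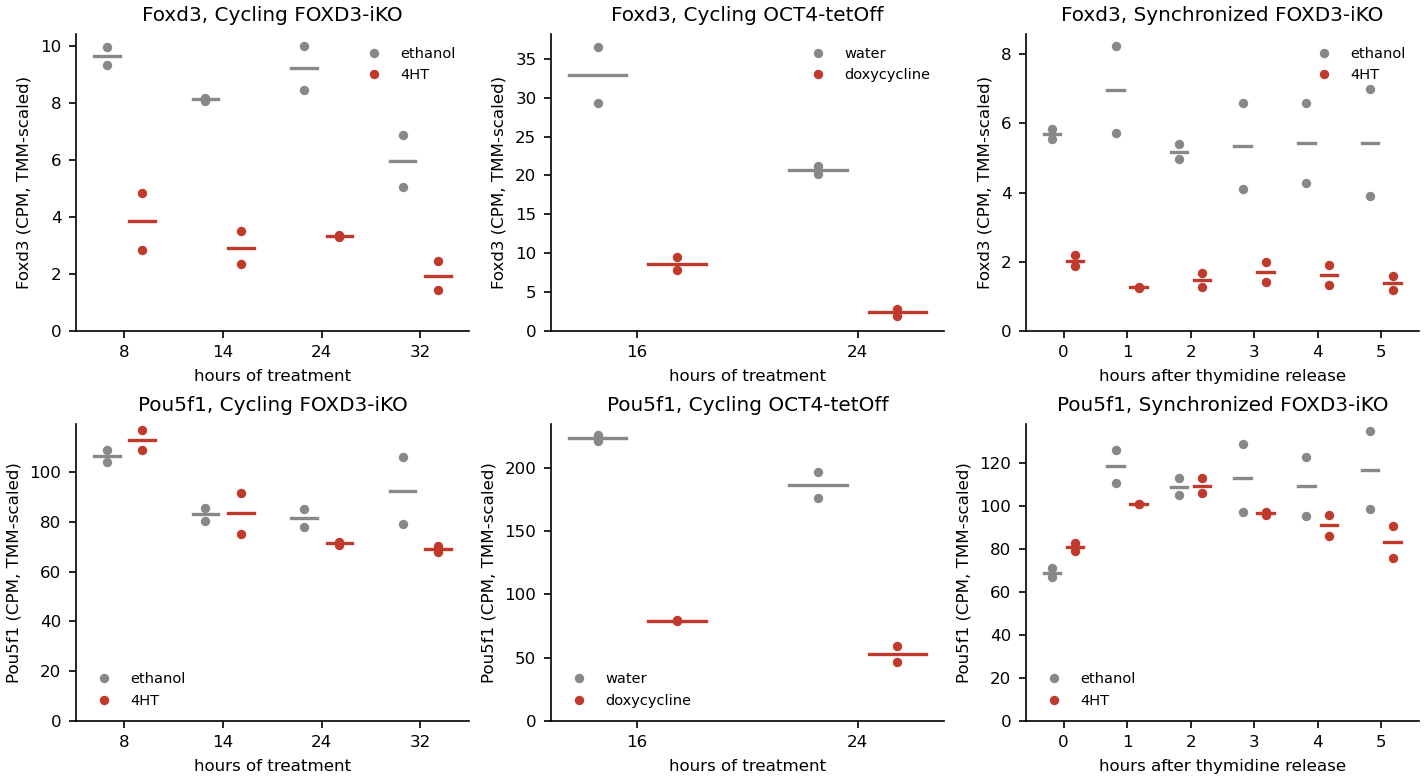
Foxd3 and Pou5f1 in CPM for each library, by experiment, time and treatment, with group means. Pou5f1 lay at 187 CPM with water and 52.6 with doxycycline at 24 h, and Foxd3 at 9.23 CPM with ethanol and 3.34 with 4HT.

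At 8 h after 4HT, Id2, an inhibitor of basic helix-loop-helix factors, rose by 1.20 ± 0.14 on the log2 scale (14.4 against 6.26 CPM, edgeR adjusted p = 0.0078). Pla2g1b, a secreted phospholipase, fell by 0.98 ± 0.10 (14.3 against 28.2 CPM, adjusted p = 0.003). They were the 2 genes called of 18707 tested, with 528 at an unadjusted p under 0.05. At 14 h the called genes were Id2 (1.18 ± 0.14, edgeR adjusted p = 0.0058), Pla2g1b (-1.06 ± 0.10, adjusted p = 0.0016) and Gm26517 (adjusted p = 0.018). Gm26517, a provisional gene named after its values were seen, had 0 and 0 counts in the ethanol libraries and 19 and 21 in the 4HT libraries. 750 genes had an unadjusted p under 0.05 at 14 h, and DESeq2 called 7. Leaving out any of the 4 libraries compared left 0 calls at 8 h, and 0 or 1 at 14 h. Without either ethanol library of 32 h, 5 genes were called at 14 h.

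Few gene lists moved at these times, and each by little. At 14 h the 26 p53 targets had a median log2 fold change of 0.10 with 0 members called (1 adjusted over the list alone), past the threshold in limma's camera (adjusted p = 0.000784) but not with an estimated correlation (adjusted p = 0.357). With total counts alone the median was -0.02. The immediate early genes, transcribed within minutes of a stimulus, had a median of 0.13 at 8 h (adjusted p = 0.000927, and 0.743 with an estimated correlation). The other lists called were cholesterol synthesis, autophagy and lysosome, histones and ribosomal proteins at 8 h, and primitive endoderm, S phase, immediate early and histones at 14 h. None held with an estimated correlation, where the smallest adjusted p was 0.421 at 8 h and 0.357 at 14 h. The histone median at 14 h, -0.27, became 0.07 without 4HT 14 h replicate 2.

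At 24 h more genes were called. Id2 rose by 1.69 ± 0.14 (19.8 against 6.18 CPM, edgeR adjusted p = 0.00019), the phospholipase C gene Plch2 by 1.38 ± 0.17 (adjusted p = 0.0043) and the adhesion gene Nectin4 by 1.37 ± 0.26 (adjusted p = 0.035). The carboxypeptidase gene Cpz rose by 1.30 ± 0.21 (edgeR adjusted p = 0.018), the leukotriene receptor gene Ltb4r2 by 1.22 ± 0.20 (adjusted p = 0.018) and the polo-like kinase gene Plk2 by 1.02 ± 0.15 (70.0 against 34.5 CPM, adjusted p = 0.01). Pla2g1b fell by 1.02 ± 0.10 (edgeR adjusted p = 0.00097) and Ttn, the gene of the giant sarcomere protein titin, by 0.82 ± 0.11 (93.3 against 165 CPM, adjusted p = 0.0057). The arginine methyltransferase gene Prmt8 fell by 0.71 ± 0.09 (edgeR adjusted p = 0.0043), the POU factor gene Pou2f3 by 0.65 ± 0.11 (23.5 against 36.9 CPM, adjusted p = 0.018) and Aldh18a1, of proline synthesis, by 0.50 ± 0.09 (adjusted p = 0.026). In all 90 of 18707 genes were called, 75 higher and 15 lower, 25 of them by more than 2-fold.

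Genes activated by the tumour suppressor p53 rose together at 24 h. Of 26 measured p53 targets 7 rose and none fell (15 adjusted over the list alone), with a median of 0.35 (limma camera adjusted p = 1.17e-21, and 0.00137 with an estimated correlation). Examples are Mdm2, the ubiquitin ligase that degrades p53 (0.65 ± 0.09, edgeR adjusted p = 0.0061), Trp53inp1 (0.60 ± 0.08, adjusted p = 0.0088) and Btg2 (0.82 ± 0.14, adjusted p = 0.018). Genes of the two-cell-like state, a rare ESC state that resembles the early embryo, had a median of 0.64 (camera adjusted p = 3.15e-05, and 0.0382 with an estimated correlation). Of 11 measured members, many in multi-copy families whose counts are uncertain, 1 rose (1 adjusted over the list alone): Zfp750, by 0.94 ± 0.17 (edgeR adjusted p = 0.031).

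Other lists called at 24 h did not hold with an estimated correlation. Of 22 immediate early genes 2 rose (2 adjusted over the list alone, median 0.20), among them Ccn1 by 0.63 ± 0.10 (edgeR adjusted p = 0.018), with a camera adjusted p of 0.000569, and an adjusted p = 0.61 with an estimated correlation. Of the 25 genes of the integrated stress response, which is driven by ATF4, 0 were called (2 higher and 7 lower adjusted over the list alone, median -0.20, camera adjusted p = 1.29e-05, and 0.197 with an estimated correlation). The 60 replication-dependent histone genes had 0 members called and a median of -0.48 (camera adjusted p = 2.57e-18, and 0.57 with an estimated correlation). Glycolysis (median -0.16), cholesterol synthesis (-0.10), ribosomal proteins (-0.08), mitochondrially encoded transcripts (-0.30) and primitive endoderm (0.08) were also called by camera, with adjusted p = 0.57, 0.595, 0.903, 0.57 and 0.566 with an estimated correlation. The 16 naive pluripotency genes (median 0.02, camera adjusted p = 0.975), the 11 neural genes (-0.02, adjusted p = 0.888) and the 11 fibroblast markers (0.04, adjusted p = 0.887) were not called.

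The count of 90 at 24 h depended on both libraries of each group. It fell steeply when any of the 24 h libraries was left out, which leaves 1 library in that group, so lost replication may account for the fall. The count also moved when a library of 32 h was left out. It was 45 with total counts outside Gm26917 and Gm42418 and 377 with the length trend removed (269 of them higher), DESeq2 called 168, and 285 were called without the low-count filter and 271 in a fit of only the compared groups.

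At 32 h many more genes were called. Ltb4r2 rose by 2.49 ± 0.23 (edgeR adjusted p = 2.5e-05), Cpz by 2.41 ± 0.25 and the thyrotropin receptor gene Tshr by 2.26 ± 0.21 (adjusted p = 2.8e-05). Neb, the gene of the muscle protein nebulin, rose by 2.19 ± 0.17 (14.5 against 3.18 CPM, edgeR adjusted p = 9.2e-06), the sodium channel subunit gene Scn3b by 2.05 ± 0.12 (10.5 against 2.54 CPM, adjusted p = 1.7e-06) and Id2 by 2.04 ± 0.17 (9.04 against 2.19 CPM, adjusted p = 1.4e-05). Cd180, a Toll-like receptor homologue, fell by 1.71 ± 0.19 (edgeR adjusted p = 0.00011) and Pla2g1b by 1.64 ± 0.10 (10.3 against 32.0 CPM, adjusted p = 1.7e-06). Of 18707 genes 913 rose and 858 fell, 467 by more than 2-fold. All 90 genes called at 24 h had the same sign at 32 h, where 73 were again called higher and 13 again lower, against 3.66 and 0.688 expected of unrelated lists.

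The p53 targets and the two-cell-like genes were called higher at 32 h too, and no list test compared 32 h with 24 h. Of 26 p53 targets 16 rose and none fell (20 adjusted over the list alone), with a median of 0.63 (limma camera adjusted p = 8.92e-21, and 0.00172 with an estimated correlation). Mdm2 rose by 1.09 ± 0.09 (edgeR adjusted p = 1.1e-05), Perp, which promotes apoptosis and cell adhesion, by 1.56 ± 0.13 (adjusted p = 1.2e-05) and Plk2 by 1.57 ± 0.15 (adjusted p = 4.4e-05). Of 11 two-cell-like genes 7 rose and none fell (9 adjusted over the list alone), with a median of 1.24 (camera adjusted p = 1.63e-08, and 0.00686 with an estimated correlation). Zfp750 rose by 1.61 ± 0.18 (edgeR adjusted p = 9.1e-05), and the multi-copy genes Zscan4d and Usp17le, whose counts are uncertain, by 1.24 ± 0.19 (adjusted p = 0.0012) and 1.48 ± 0.32 (adjusted p = 0.01). Both lists were called under every setting tried at 24 and 32 h.

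12 further lists were called by camera at 32 h and none of these held with an estimated correlation. Of 15 primitive endoderm genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.15, camera adjusted p = 0.00133, and 0.126 with an estimated correlation). They include the regulators Hnf4a (1.07 ± 0.12, edgeR adjusted p = 0.00012) and Gata6 (1.08 ± 0.14, adjusted p = 0.00038). Of 20 germline genes 3 rose and 1 fell (the same adjusted over the list alone, median 0.29, camera adjusted p = 0.00228, and 0.133 with an estimated correlation). Hormad1, of the meiotic chromosome axis, rose by 0.77 ± 0.11 (edgeR adjusted p = 0.00069). Of 19 glycolysis genes 13 fell and none rose (14 lower adjusted over the list alone, median -0.42, camera adjusted p = 1.34e-10, and 0.11 with an estimated correlation). Among them were Pgk1 (-0.65 ± 0.08, edgeR adjusted p = 0.00024) and Tpi1 (-0.98 ± 0.13, adjusted p = 0.00049). Of 15 WNT response genes 4 fell and 1 rose (8 lower and 1 higher adjusted over the list alone, median -0.45, camera adjusted p = 0.00295, and 0.088 with an estimated correlation). Axin2, a negative feedback target, fell by 0.45 ± 0.08 (edgeR adjusted p = 0.0039), and the receptor ligase gene Rnf43 rose by 0.88 ± 0.15 (adjusted p = 0.0031). Of 37 genes of DNA replication and S phase 6 fell (15 adjusted over the list alone, median -0.23, camera adjusted p = 9.37e-08, and 0.088 with an estimated correlation).

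Histones and ribosomal proteins were lower at 32 h. Of 60 replication-dependent histone genes 50 fell (57 adjusted over the list alone, median -1.15, and -0.66 once the length trend was removed, camera adjusted p = 7.3e-34, and 0.133 with an estimated correlation). Of 81 genes of cytosolic ribosomal proteins 41 fell (74 adjusted over the list alone, median -0.41, and -0.15 once the length trend was removed, camera adjusted p = 4.69e-25, and 0.317 with an estimated correlation). Both are multi-copy families with uncertain counts. Fold changes at 32 h correlated with gene length across genes, which are not independent replicates (Spearman rho 0.30). Of 16 naive pluripotency genes 3 fell (3 adjusted over the list alone, median -0.20, and 0.00 with total counts alone, camera adjusted p = 0.0398, and 0.367 with an estimated correlation). Nr0b1 fell by 0.70 ± 0.15 (edgeR adjusted p = 0.0095). The naive list was not called without ethanol 32 h replicate 2 (median -0.10) or 4HT 32 h replicate 2 (-0.13). Formative and primed epiblast (median -0.17), integrated stress response (-0.27), ribosome biogenesis (-0.16) and cholesterol synthesis (-0.20) were called lower too, with adjusted p = 0.13, 0.229, 0.367 and 0.143 with an estimated correlation.

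The count of 1771 at 32 h was 4494 without ethanol 32 h replicate 1, 604 without 4HT 32 h replicate 1 and 572 without 4HT 32 h replicate 2. That ethanol library resembled the 4HT libraries in its share of Gm26917 and Gm42418. Scaling by total counts shifted the median of all genes by 0.17 and called 1802 genes, 1564 of them higher. Outside Gm26917 and Gm42418 it was 1094, 805 higher. A fit of only the compared groups called 201 genes. With the length trend removed 2611 were called, 1470 of them among the 1771.

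The size of the FOXD3 response differed between the 4 times at 85 genes (edgeR, 1802 at an unadjusted p under 0.05). The smallest p-values were those of Scn3b, whose response at 32 h exceeded that at 8 h by 1.99 (adjusted p = 0.0014), Arhgef33 (1.85, adjusted p = 0.0014) and Zfp365 (1.16, adjusted p = 0.0015), with Neb (2.25, adjusted p = 0.0023), the clock gene Arntl2 (1.40, adjusted p = 0.0035), Perp (1.65, adjusted p = 0.004) and Pou2f3 (-1.14, adjusted p = 0.0079). 6 of 26 p53 targets were among the 85 genes (15 adjusted over the list alone) and 1 of 11 two-cell-like genes. Library names in the labels put 8 and 14 h in one numbered series and 24 and 32 h in another, so time and series cannot be told apart for differences of 8 or 14 h from 24 or 32 h. Leaving out 1 library gave from 11 (4HT 32 h replicate 2) to 774 (ethanol 32 h replicate 1) genes, and 14 of the 16 libraries each moved the count by over 1.5 times. DESeq2 called 299 genes, no low-count filter gave 600, total counts alone 224, the length trend removed 398 and total counts outside Gm26917 and Gm42418 53.

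Loss of OCT4 was examined at 16 and 24 h. At 16 h Gadd45g, a growth arrest gene, rose by 3.72 ± 0.24 (edgeR adjusted p = 1.6e-05) and the potassium channel gene Kcnc1 by 3.64 ± 0.19. The epithelial keratin gene Krt7 rose by 3.32 ± 0.35 and the zinc finger gene Zfp703 by 3.19 ± 0.16. Aoah, a lipase that inactivates bacterial lipopolysaccharide, fell by 5.33 ± 0.13 (1.15 against 46.7 CPM, edgeR adjusted p = 8.1e-08), Pou2f3 by 4.41 ± 0.28 and the guidance cue gene Ntn1 by 3.32 ± 0.19 (24.7 against 247 CPM). Of 17713 genes 1407 rose and 1579 fell, 1280 by more than 2-fold. Of 15 naive pluripotency genes 12 fell (13 adjusted over the list alone, median -1.07, limma camera adjusted p = 1.24e-11, and 0.22 with an estimated correlation). Tfcp2l1 fell by 1.87 ± 0.11 (edgeR adjusted p = 1.1e-05). Of 16 primitive endoderm genes 8 rose and 2 fell (8 and 3 adjusted over the list alone, median 0.73, camera adjusted p = 0.000381, and 0.22 with an estimated correlation). Gata6 rose by 2.48 ± 0.16 (edgeR adjusted p = 1.5e-05) and the basement membrane collagen gene Col4a1 by 2.16 ± 0.13 (adjusted p = 1.2e-05). Of 20 trophectoderm genes 10 rose and 2 fell (12 and 2 adjusted over the list alone, median 0.71, camera adjusted p = 0.003, and 0.527 with an estimated correlation). Gata3 rose by 1.55 ± 0.11 (edgeR adjusted p = 2.6e-05). 10 lists were called at 16 h, and none held with an estimated correlation, where the smallest adjusted p was 0.22. The count of 2986 was 1332 and 1371 without water 16 h replicates 1 and 2, and 1429 and 1375 without doxycycline 16 h replicates 1 and 2. With the length trend removed it was 5337, and scaling by total counts shifted the median of all genes by 0.15 and called 3410 genes, 2392 of them higher.

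At 24 h of OCT4 loss Kcnc1 rose by 5.31 ± 0.17 (30.8 against 0.759 CPM, edgeR adjusted p = 3.9e-07) and Gadd45g by 4.39 ± 0.24 (adjusted p = 2.6e-06). The imprinted retrotransposon-derived gene Peg10 rose by 4.15 ± 0.15 (1050 against 58.9 CPM, edgeR adjusted p = 5.8e-07) and Gata6, a regulator of primitive endoderm, by 4.10 ± 0.16 (20.9 against 1.21 CPM, adjusted p = 6e-07). Aoah fell by 6.46 ± 0.14 (0.55 against 49.0 CPM, edgeR adjusted p = 3.1e-08) and Pou2f3 by 4.76 ± 0.24 (adjusted p = 2.1e-06). The nodal antagonist gene Lefty2 fell by 4.58 ± 0.25 (edgeR adjusted p = 2.6e-06), the chromatin factor gene Utf1 by 4.36 ± 0.33 (adjusted p = 1.5e-05) and the arginine transporter gene Slc7a3 by 4.28 ± 0.20. Of 17713 genes 3210 rose and 3321 fell, 2453 by more than 2-fold. 1235 genes were called higher and 1370 lower at both times, where 255 and 296 would be expected of unrelated lists.

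At 24 h of OCT4 loss pluripotency lists were called lower and extraembryonic lists higher, none with an estimated correlation. Of 15 naive pluripotency genes 14 fell (14 adjusted over the list alone), with a median of -1.57 (limma camera adjusted p = 3.31e-09, and 0.205 with an estimated correlation). Tcl1, a kinase co-activator, fell by 4.09 ± 0.21 (edgeR adjusted p = 2.1e-06) and the orphan receptor gene Esrrb by 1.57 ± 0.12 (adjusted p = 1.4e-05). Of 13 core pluripotency genes 9 fell and 1 rose (the same adjusted over the list alone, median -0.60, camera adjusted p = 0.000922, and 0.265 with an estimated correlation). Lin28a, which blocks let-7 maturation, rose by 2.34 ± 0.14 (edgeR adjusted p = 4.4e-06). Of 20 trophectoderm genes 12 rose and 2 fell (13 and 2 adjusted over the list alone, median 1.01, camera adjusted p = 0.00101, and 0.302 with an estimated correlation). Gata3 rose by 2.32 ± 0.11 (edgeR adjusted p = 1.6e-06). Of 16 primitive endoderm genes 10 rose and 2 fell (median 1.08, camera adjusted p = 0.000326, and 0.205 with an estimated correlation). Col4a1 rose by 2.46 ± 0.13 (edgeR adjusted p = 2.3e-06). Of 23 imprinted genes 12 rose and 2 fell (13 and 2 adjusted over the list alone, median 0.69, camera adjusted p = 0.000168, and 0.205 with an estimated correlation). Of 18 germline genes 9 rose and 3 fell (11 and 3 adjusted over the list alone, median 0.44, camera adjusted p = 0.0102, and 0.265 with an estimated correlation). The germ cell helicase gene Ddx4 rose by 1.40 ± 0.12 (edgeR adjusted p = 3e-05).

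Lists of DNA replication, of mitosis and others were called lower at 24 h of OCT4 loss, none with an estimated correlation. Of 37 genes of DNA replication and S phase 36 fell (median -0.66, limma camera adjusted p = 4e-15, and 0.205 with an estimated correlation). The replication initiator Mcm10 fell by 1.12 ± 0.10 (edgeR adjusted p = 2.9e-05). Of 39 genes of G2 and mitosis 31 fell (median -0.41, camera adjusted p = 4.46e-09, and 0.205 with an estimated correlation). The kinesin gene Kif2c fell by 0.55 ± 0.08 (edgeR adjusted p = 0.00093). DNA damage signalling and repair (16 of 31 lower, 1 higher, median -0.31), ribosome biogenesis (24 of 41 lower, 1 higher, -0.38), glycolysis (13 of 19 lower, 4 higher, -0.60) and the integrated stress response (11 of 25 lower, 1 higher, -0.42) were called lower, with adjusted p = 0.205, 0.302, 0.421 and 0.302 with an estimated correlation. FGF and ERK response (7 of 15 lower, 2 higher, median -0.27), with the ERK phosphatase gene Dusp6 at -1.81 ± 0.18 (edgeR adjusted p = 8.6e-05), and TGF-beta and nodal response (6 of 12 lower, 1 higher, -0.57), with Id3 at -2.98 ± 0.17 (edgeR adjusted p = 3.1e-06), had adjusted p = 0.265 and 0.338 with an estimated correlation. Histones (52 of 58 lower, median -1.33) and ribosomal proteins (70 of 82 lower, -0.55), both uncertain as multi-copy families, had adjusted p = 0.421 and 0.482 with an estimated correlation. Mitochondrially encoded transcripts (7 of 20 lower, median -0.71, adjusted p = 0.519 with an estimated correlation) turned to 0.19 once the length trend was removed and were not called without water 24 h replicate 1 (-0.32) or doxycycline 24 h replicate 2 (-0.45). Fold changes correlated with gene length across genes (Spearman rho 0.31).

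16 lists were not called at 24 h of OCT4 loss, and members of several changed in both directions. Of 26 p53 targets 6 rose and 4 fell (median 0.24, limma camera adjusted p = 0.315), and of 12 mesoderm genes 2 rose and 7 fell (-1.14, 0.121). Of 15 WNT response genes 7 rose and 4 fell (0.70, 0.215), of 12 formative and primed epiblast genes 3 rose and 6 fell (-0.08, 0.445), and of 21 apoptosis regulators 8 rose and 1 fell (0.18, 0.0527). Of the lists that mark other cell types, 4 of 10 fibroblast genes rose and 5 fell (median -0.57, camera adjusted p = 0.813), 2 of 9 blood and endothelial genes rose and 4 fell (-0.67, 0.315), and 1 of 8 neural genes rose (0.34, 0.277). The medians and camera adjusted p-values of the others were -0.02 and 0.789 for two-cell-like genes, 0.20 and 0.507 for immediate early genes, -0.17 and 0.0558 for heat shock, -0.07 and 0.683 for transcription elongation, -0.14 and 0.13 for chromatin remodelling, 0.00 and 0.999 for cholesterol synthesis, 0.37 and 0.215 for interferon response, and 0.10 and 0.486 for autophagy. The count of 6531 was 3977 without water 24 h replicate 1.

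Whether the response to OCT4 loss differed between 16 and 24 h gene by gene depended on the setting. The edgeR test called 0 of 17713 genes (smallest adjusted p 0.11), with 1952 at an unadjusted p under 0.05. DESeq2 called 90, RLE factors gave 0, total counts alone 50, no low-count filter 457 and the length trend removed 600. The fold changes of both times correlated across genes (Pearson r 0.82). As lists, 16 differed by camera, 13 of them also with the length trend removed and none with an estimated correlation. Among them S phase (median difference -0.46), G2 and mitosis (-0.37) and histones (-1.16) were lower at 24 h, with camera adjusted p = 0.19, 0.19 and 0.35 with an estimated correlation. The differences between the times correlated with gene length across genes (Spearman rho 0.38). Without doxycycline 24 h replicate 1 the count was 151, and without doxycycline 24 h replicate 2 it was 3.

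**Figure D2:**
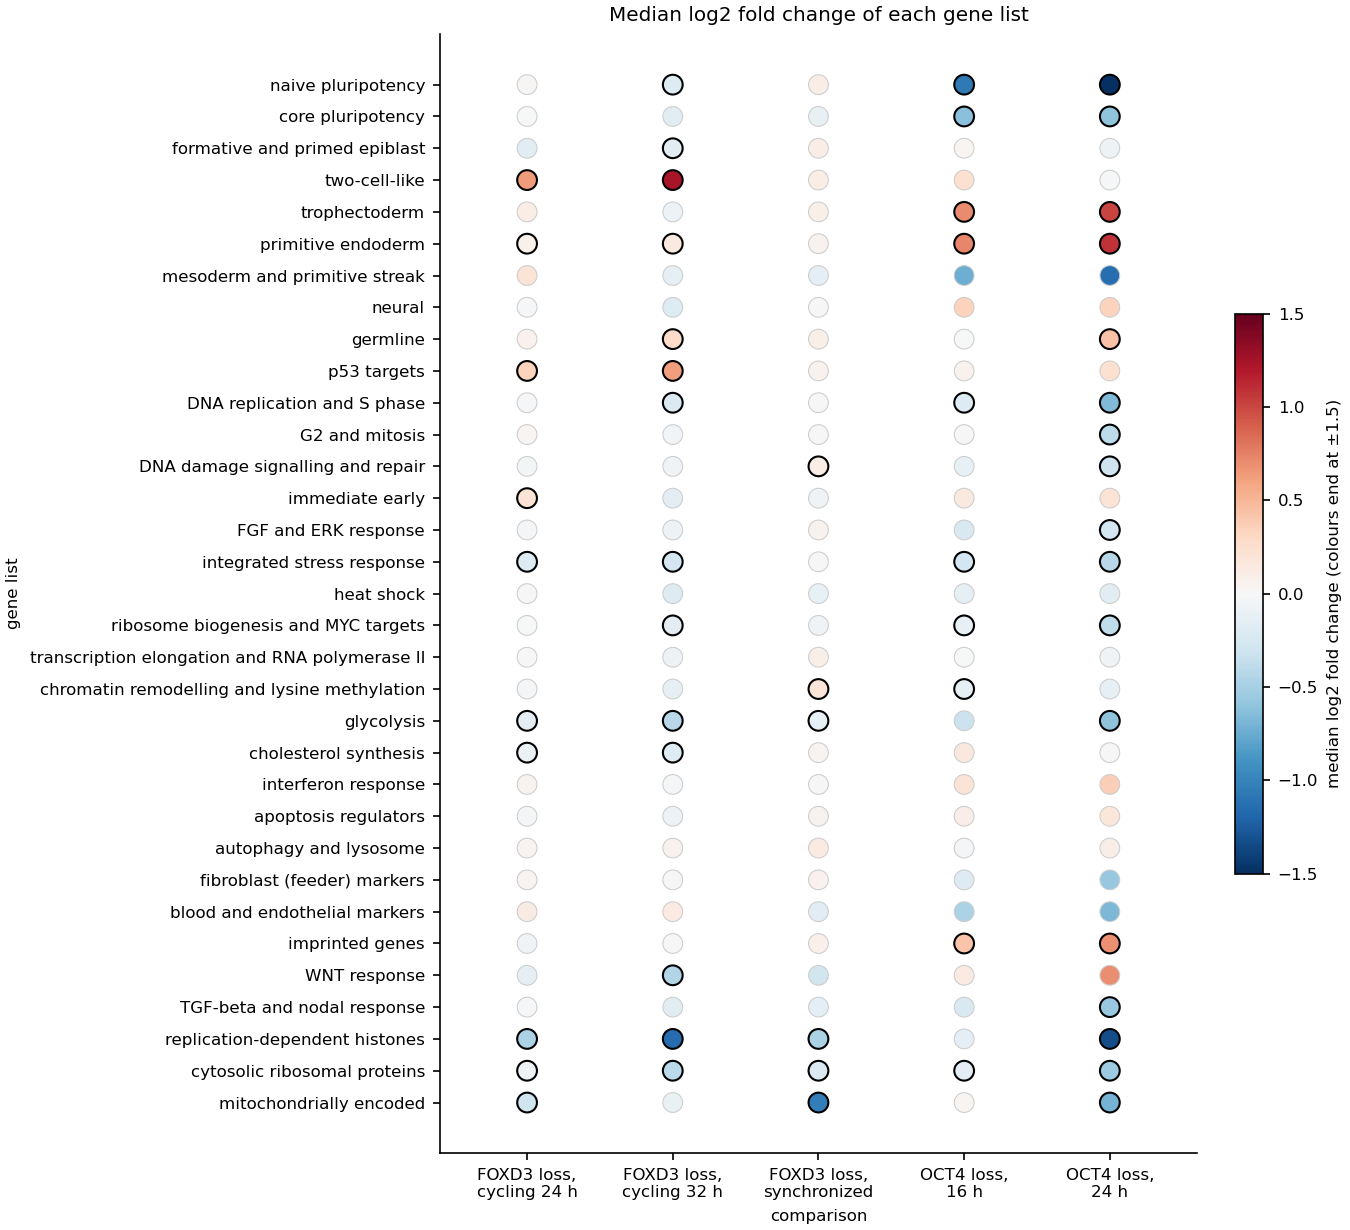
Median log2 fold change of each of the 33 gene lists (vertical axis) after FOXD3 loss at 24 and 32 h and in synchronized cells and after OCT4 loss at 16 and 24 h (horizontal axis), as coloured dots, with a black outline where limma's camera called the list. p53 targets lay at 0.35 and 0.63 after 24 and 32 h of FOXD3 loss, and naive pluripotency at -1.57 after 24 h of OCT4 loss and 0.02 after 24 h of FOXD3 loss.

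FOXD3 loss and OCT4 loss were compared at 24 h in a joint fit. 3038 of 18437 genes differed in their response, 1673 with the FOXD3 response higher and 1365 with it lower. Relative to OCT4 loss, FOXD3 loss left Aoah 6.67 ± 0.21 higher on the log2 scale (edgeR adjusted p = 3e-07), Slc7a3 4.09 ± 0.21 higher, the cytokine signalling inhibitor gene Socs2 2.84 ± 0.14 higher (adjusted p = 5.6e-06) and Peg10 lower (-3.81 ± 0.22, adjusted p = 9.3e-06). Foxd3 and Pou5f1 were 1.67 ± 0.26 and 1.64 ± 0.19 higher (edgeR adjusted p = 0.0019 and 0.00034). Of 16 naive pluripotency genes 13 differed, all higher (median 1.47, limma camera adjusted p = 4.85e-10, and 0.176 with an estimated correlation). Tcl1 differed by 3.87 ± 0.25 (edgeR adjusted p = 1.2e-05). Of 13 core pluripotency genes 7 were higher and 1 lower (median 0.66, camera adjusted p = 9.4e-05, and 0.269 with an estimated correlation). Of 16 primitive endoderm genes 2 were higher and 7 lower (median -0.79, camera adjusted p = 0.000489, and 0.176 with an estimated correlation). Gata6 differed by -3.67 ± 0.21 (edgeR adjusted p = 9.4e-06). Of 37 S phase genes 27 were higher (median 0.66, camera adjusted p = 1.53e-13, and 0.198 with an estimated correlation). Of 26 p53 targets 6 were higher and 1 lower (7 and 2 adjusted over the list alone, median 0.24, camera adjusted p = 0.0411, and 0.452 with an estimated correlation). Psrc1 was higher by 1.09 ± 0.17 (edgeR adjusted p = 0.002) and the cell cycle inhibitor Cdkn1a lower (-1.10 ± 0.18, adjusted p = 0.0029). The p53 call was lost without any of 6 libraries, with adjusted p-values up to 0.062. 18 lists differed in all, none with an estimated correlation. The lines, drugs and library series differ between the 2 experiments, so these differences are also differences between experiments.

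The count of 3038 was 1436 and 1738 without ethanol 24 h replicates 1 and 2, and 2000 and 1524 without 4HT 24 h replicates 1 and 2. It was 1876 without water 24 h replicate 1 and 4870 without doxycycline 24 h replicate 1. Of the genes called in both, 18 rose with FOXD3 loss and with OCT4 loss at 24 h, against 12.4 expected of unrelated lists (Fisher's exact test, one-sided, p = 0.061), and 11 fell in both against 2.85 (exact p = 7.3e-06). These 29 shared calls were 1 and 2 without ethanol 24 h replicates 1 and 2, and 7 and 2 without 4HT 24 h replicates 1 and 2. Across 17226 genes, which are not independent, the fold changes had a Pearson r of 0.16 and a Spearman rho of 0.13. Between FOXD3 loss at 32 h and OCT4 loss at 24 h the shared calls were 273 higher and 479 lower, against 152 and 161 expected. The times differ, and both sets of fold changes correlated with gene length (Spearman rho 0.30 and 0.31). These shared calls can therefore not be assigned to the loss of the 2 factors alone.

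In synchronized cells the 4HT effect was estimated over all 6 release times (12 libraries per arm). An arm holds 2 numbered replicates at each time. Deviations of same-numbered libraries correlated between times, up to 0.72 for ethanol 3 and 4 h. The 12 libraries may therefore not be independent samples, which these p-values take them to be. Atp8b4, a phospholipid flippase gene, rose by 1.37 ± 0.10 (20.6 against 7.84 CPM, edgeR adjusted p = 2.8e-09), the receptor kinase gene Ror1 by 1.36 ± 0.12 and the cystine transporter subunit gene Slc7a9 by 1.34 ± 0.08 (adjusted p = 2.1e-10). Id2 rose by 1.25 ± 0.09 (7.79 against 3.22 CPM, edgeR adjusted p = 2.6e-09), Tfap2c, the AP-2 gamma factor of germ cells and trophoblast, by 1.22 ± 0.07 (27.7 against 11.9 CPM, adjusted p = 9.3e-11) and the junction gene Cgnl1 by 1.10 ± 0.05 (73.6 against 34.2 CPM, adjusted p = 2e-11). Pla2g1b fell by 1.39 ± 0.10 (5.7 against 14.9 CPM, edgeR adjusted p = 1.6e-09) and Cd180 by 1.22 ± 0.10 (adjusted p = 1.9e-08). The mitochondrial genes mt-Nd2 and mt-Cytb fell by 1.24 ± 0.14 (241 against 567 CPM, edgeR adjusted p = 2.2e-06) and by 1.07 ± 0.12 (403 against 834 CPM, adjusted p = 1.2e-06). Of 17739 genes 3301 rose and 3265 fell, yet only 99 by more than 2-fold.

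Transcripts encoded in mitochondrial DNA had the largest median change of the lists in synchronized cells. Of 21 measured 19 fell and none rose (19 adjusted over the list alone), with a median of -1.04 (limma camera adjusted p = 9.78e-12, and 0.509 with an estimated correlation). Their share of all counts was 0.389 to 0.972% in the ethanol libraries and 0.152 to 0.348% in the 4HT libraries. Of 65 histone genes 49 fell (50 adjusted over the list alone, median -0.47, camera adjusted p = 9.01e-15, and 0.653 with an estimated correlation). Of 81 ribosomal protein genes 55 fell (61 adjusted over the list alone, median -0.23, camera adjusted p = 3.5e-16, and 0.703 with an estimated correlation). Of 19 glycolysis genes 10 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.13, camera adjusted p = 0.00242, and 0.703 with an estimated correlation). Ldha fell by 0.57 ± 0.06 (edgeR adjusted p = 6.2e-07). Of 30 chromatin remodelling genes 17 rose and 2 fell (19 and 2 adjusted over the list alone, median 0.19, and -0.01 with total counts alone, camera adjusted p = 0.000253, and 0.653 with an estimated correlation). Arid1a, a BAF complex subunit, rose by 0.41 ± 0.07 (edgeR adjusted p = 8.5e-05). Of 31 DNA damage genes 9 rose (9 adjusted over the list alone, median 0.10, and -0.10 with total counts alone, camera adjusted p = 0.0197, and 0.653 with an estimated correlation). Fancm, of the Fanconi pathway, rose by 0.42 ± 0.07 (edgeR adjusted p = 0.0001).

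The p53 targets were not called in synchronized cells: 8 of 26 rose and 4 fell (8 and 5 adjusted over the list alone, median 0.05, limma camera adjusted p = 0.449). Ptpn14 rose by 0.51 ± 0.05 (edgeR adjusted p = 4.9e-07) and Mdm2 by 0.26 ± 0.04 (adjusted p = 0.00014). Neither were the two-cell-like genes (2 of 15 higher, median 0.11, camera adjusted p = 0.392) or the naive pluripotency genes (5 of 16 higher and 3 lower, 0.10, 0.449). Fold changes correlated with gene length across genes (Spearman rho 0.47), and with the length trend removed 4342 genes were called, 3343 of them among the 6566. Of the 6 lists called by camera over all release times, 5 held with that trend removed. Scaling by total counts shifted the median of all genes by -0.20 and called 8206 genes, 791 of them higher. Outside Gm26917 and Gm42418 the shift was -0.16 and 1297 of 7500 were higher.

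At the single release times, with 2 libraries per arm, edgeR called 79 genes at 0 h (69 higher, 10 lower), 425 at 1 h (322 and 103) and 140 at 2 h (93 and 47). It called 619 at 3 h (404 and 215), 92 at 4 h (65 and 27) and 393 at 5 h (175 and 218). These divisions turned with the scaling: with total counts outside Gm26917 and Gm42418, 21 of 61 were higher at 1 h, 21 of 55 at 2 h and 258 of 1322 at 3 h, and with RLE factors 291 of 410 at 5 h. Id2 was higher at 0 h (1.52, adjusted p = 0.00069) and at 5 h (1.72 ± 0.22, adjusted p = 0.00076). Pla2g1b fell at all 6 times, by 1.95 ± 0.21 at 5 h (edgeR adjusted p = 0.00023). The laminin gene Lama1 rose by 1.24 ± 0.11 at 5 h (159 against 67.1 CPM, adjusted p = 6.1e-05). Lefty1, a nodal antagonist, fell by 1.35 ± 0.25 at 5 h (adjusted p = 0.012). Mitochondrially encoded transcripts were called lower by camera at each time, with medians of -1.16, -0.83, -1.21, -1.03, -0.83 and -0.79 from 0 to 5 h, and adjusted p = 0.239, 0.789, 0.611, 0.527, 0.421 and 0.587 with an estimated correlation. No list called at a single release time held with an estimated correlation. Leaving out 1 of the 4 libraries compared gave 5 to 26, 13 to 348, 18 to 48, 21 to 3710, 16 to 112 and 43 to 102 genes from 0 to 5 h, the 3710 without ethanol 3 h replicate 2.

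For differences of the 4HT response between release times edgeR called 0 of 17739 genes, with 883 at an unadjusted p under 0.05. DESeq2 also called 0, but 1738 were called without the low-count filter. Where simulated genes changed at release 1 h alone, the test called 0.0% of those changed 2-fold and 43.9% of those changed 3-fold. Smaller differences confined to that time were thus not detectable here, and differences lasting over several release times were not simulated. Of the 90 genes called in cycling cells at 24 h, 38 were also called higher and 13 also lower in synchronized cells, against 14.3 and 2.8 expected of unrelated lists (Fisher's exact test, one-sided, p = 7e-10 and 2.4e-08), and 73 had the same sign. These 51 shared calls were 2 and 5 without ethanol 24 h replicates 1 and 2, and 14 and 4 without 4HT 24 h replicates 1 and 2. These shared genes come from separate tables with separate controls.

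**Figure D3:**
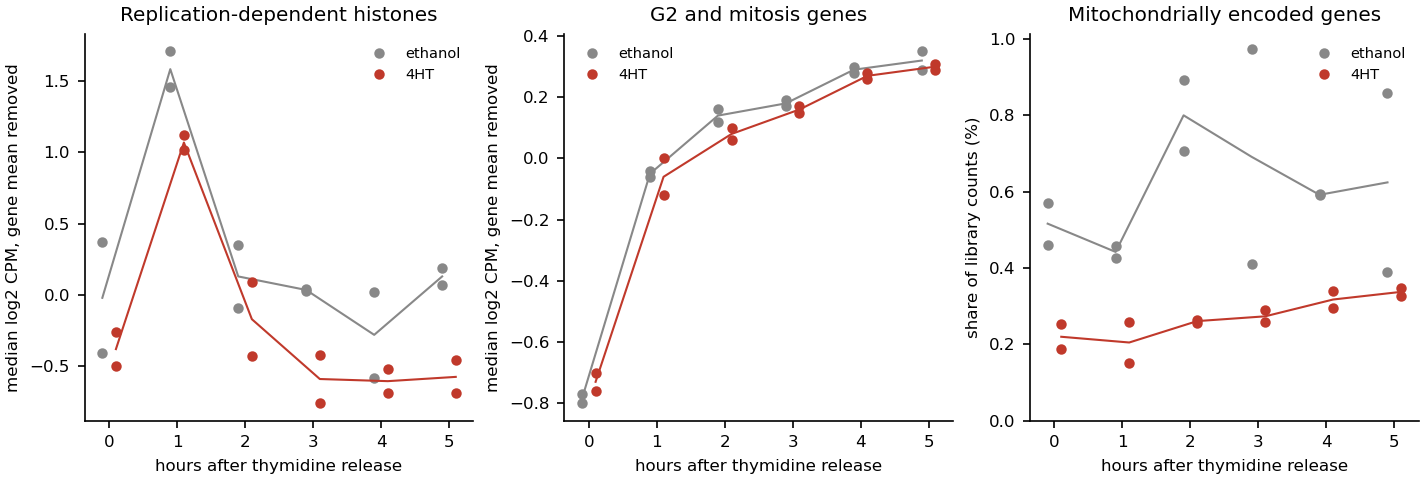
Median log2 CPM of histones and of G2 and mitosis genes, each gene's mean over the synchronized libraries removed, and the percent of counts from mitochondrially encoded genes, against hours of release, with a point per library and lines through the arm means. Histones at 1 h lay at 1.46 and 1.71 with ethanol and at 1.12 and 1.02 with 4HT, and the mitochondrial share was 0.389 to 0.972% with ethanol and 0.152 to 0.348% with 4HT.

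Release from the thymidine block gave a course of its own in the ethanol arm. Between 0 and 1 h the replication-dependent histones rose: 60 of 65 were called higher (62 adjusted over the list alone, median 1.59, limma camera adjusted p = 1.44e-40, and 0.159 with an estimated correlation). Hist1h2bh rose by 3.26 ± 0.36 (15.4 against 1.74 CPM, edgeR adjusted p = 5.6e-05) and Hist1h1e by 2.58 ± 0.29 (40.2 against 6.86 CPM). Of 39 genes of G2 and mitosis 28 rose (31 adjusted over the list alone, median 0.71, camera adjusted p = 2.33e-24, and 6.56e-05 with an estimated correlation). The mitotic kinase gene Plk1 rose by 1.64 ± 0.13 (edgeR adjusted p = 4.9e-06). Of 81 ribosomal protein genes 55 rose (67 adjusted over the list alone, median 0.48, camera adjusted p = 8.66e-21, and 0.373 with an estimated correlation). Of 26 p53 targets 6 fell and 1 rose (13 and 3 adjusted over the list alone, median -0.31, camera adjusted p = 0.0215, and 0.159 with an estimated correlation). Ribosome biogenesis (median 0.35), glycolysis (0.32), heat shock (0.34), core pluripotency (0.29), transcription elongation (0.28) and chromatin remodelling (0.22) also rose by camera, with adjusted p = 0.159, 0.216, 0.187, 0.332, 0.373 and 0.495 with an estimated correlation. Fold changes correlated with gene length across genes (Spearman rho -0.42), and 8 of the 10 lists called by camera held with the length trend removed. In the 4HT arm that correlation was 0.09. Ribosomal protein medians per 4HT library, each gene's mean removed, were -0.08 and -0.08 at 0 h and -0.15 and -0.02 at 1 h. Pou5f1 rose by 0.78 ± 0.16 (edgeR adjusted p = 0.0051), and the serotonin receptor gene Htr4 fell by 2.51 ± 0.47 (adjusted p = 0.0027). In all 1842 genes rose and 1407 fell at 1 h. This count of 3249 was 1800 and 702 without ethanol 0 h replicates 1 and 2, 1313 and 1161 without ethanol 1 h replicates 1 and 2, and 5050 and 5032 without ethanol 3 h replicates 1 and 2. Scaling by total counts called 1736 genes, 649 of them higher.

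In the 4HT arm histones (47 of 65 higher, 60 adjusted over the list alone, median 1.46, limma camera adjusted p = 1.22e-43, and 0.128 with an estimated correlation) and genes of G2 and mitosis (25 of 39 higher, 35 adjusted over the list alone, median 0.71, camera adjusted p = 3.33e-35, and 9.19e-06 with an estimated correlation) rose in the same interval. The p53 targets fell: 6 of 26 were called lower (11 adjusted over the list alone, median -0.31, camera adjusted p = 1.66e-05, and 0.00855 with an estimated correlation). Btg2 fell by 0.77 ± 0.13 (edgeR adjusted p = 0.0028). The immediate early list was called lower by camera only with the preset correlation (8 of 23 genes fell, 11 adjusted over the list alone, median -0.41, camera adjusted p = 8.08e-06, and 0.375 with an estimated correlation). Fos, an AP-1 subunit, fell by 1.87 ± 0.32 (edgeR adjusted p = 0.0028). Of all genes 565 rose and 528 fell at 1 h, and 382 of these were called higher and 292 lower in the ethanol arm too, against 58.7 and 41.9 expected. The count of 1093 was 344 and 395 without 4HT 0 h replicates 1 and 2 and 260 without 4HT 1 h replicate 2, and 93 of 341 were higher with total counts alone.

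Over the full course 3441 genes changed in the ethanol arm and 2727 in the 4HT arm (edgeR). In the ethanol arm the cell cycle-linked RNA gene Lockd rose by up to 3.75 (adjusted p = 7.8e-10) and the membrane protein gene Emp1 by 3.74 (adjusted p = 1.2e-08), while Fos (-3.06, adjusted p = 7.2e-05) and S100a13 (-2.31, adjusted p = 2.3e-07) fell. In the 4HT arm Emp1 rose by up to 3.87 (edgeR adjusted p = 3.4e-08), and Fos (-4.66, adjusted p = 1.7e-05), Junb (-2.31, adjusted p = 0.0055) and Atf3 (-2.25, adjusted p = 2.4e-06), all of the AP-1 and ATF family, fell. Of 39 genes of G2 and mitosis 36 rose in each arm (38 with ethanol and 37 with 4HT adjusted over the list alone), and of 23 immediate early genes 9 fell with ethanol and 14 with 4HT. The difference between the arms was not tested for lists over the course. Leaving out ethanol 0 h replicates 1 or 2 or ethanol 3 h replicate 2 gave 1647, 1320 and 7649 genes in the ethanol arm, and leaving out 4HT 0 h replicates 1 or 2 gave 1172 and 1473 in the 4HT arm.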

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

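The joint fit of cycling and synchronized cells and the tests of the 3 patterns weighed here were chosen after the results were seen, except the comparison of synchronized with cycling ethanol cells for p53 targets, whose bounds were written first. The differences between times and between FOXD3 and OCT4 loss were planned.

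These results stand out because a response differed between groups by a test of the difference itself. The FOXD3 response differed between 8, 14, 24 and 32 h at 85 genes (edgeR), or 11 to 774 with a library left out. FOXD3 loss and OCT4 loss at 24 h differed at 3038 genes, with p53 targets 0.24 and naive pluripotency genes 1.47 higher in median log2 response to FOXD3 loss, neither list holding with an estimated correlation. The 4HT response of cycling cells differed from that of synchronized cells at 44 of 18987 genes at 24 h (34 higher, 10 lower) and at 517 genes at 32 h (443 higher, 74 lower). At 32 h the cycling response exceeded the synchronized one by 0.55 for p53 targets (limma camera adjusted p = 6.4e-19, and 8.7e-05 with an estimated correlation), by 1.10 for two-cell-like genes (adjusted p = 7.2e-07, and 0.046) and by 1.04 for mitochondrially encoded transcripts (adjusted p = 9.1e-08, and 0.2). Against the same synchronized average, the cycling response at 24 h differed by 0.31 for p53 targets (camera adjusted p = 5.3e-08, and 0.015 with an estimated correlation). The difference was 0.36 for two-cell-like genes, not called (camera adjusted p = 0.18, and 0.77), and 0.79 for mitochondrially encoded transcripts (adjusted p = 6.8e-07, and 0.5). In ethanol cells the two-cell-like members that passed the synchronized table's filter were already 3.40 higher in synchronized cells than in cycling cells at 24 h (median log2 difference). Their responses to 4HT are therefore compared from unlike starting levels, and these differences cannot be assigned to FOXD3 loss alone. The block was lifted 24 h after 4HT, so the later release times are not matched in time. Groups of 2 libraries were not tested for single outlying libraries.

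The first pattern is the rise of p53 targets after 4HT in cycling cells. It is not explained by a trend with gene length, since the median at 32 h was 0.64 with the trend removed, nor by ethanol 32 h replicate 1, since it was 0.59 without it. DNA damage or toxicity from 4HT or the recombinase it activates could raise p53 targets apart from FOXD3; synchronized cells had the drug as well and responded less at 24 h, by 0.31 (edgeR members: 4 of 26; camera adjusted p = 5.3e-08, and 0.015 with an estimated correlation). That comparison leaves the explanation open, because the block may have raised the list beforehand, and labelling time and table differ too. Over all release times the list was 0.34 higher in synchronized ethanol cells than in cycling ethanol cells at 24 h (camera adjusted p = 0.0056, and 0.27 with an estimated correlation). This is just under the rise after 4HT in cycling cells at 24 h. With the length trend removed the difference was 0.46, and 0.70 at release 0 h. Loss of FOXD3 stays open as a biological explanation, and no cells treated with 4HT but keeping FOXD3 were analysed here.

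The second pattern is the lower level of mitochondrially encoded transcripts after 4HT in synchronized cells. A trend with gene length is not its whole cause, since 18 of 21 members were called lower with the trend removed. An effect of FOXD3 loss in any culture would lower the list in cycling cells by a like amount. The cycling response at 32 h and the synchronized response over all release times differed by 1.04. Only 1 of 21 members differed one by one, which does not show that the falls were alike. In cycling cells the mitochondrial share at 24 h was 1.19 and 1.23% with ethanol and 0.97 and 1.05% with 4HT. At 32 h the shares were 0.984 and 0.87% against 0.995 and 0.987%. The list's medians per library, each gene's mean removed, were then -0.13 and -0.35 against -0.35 and -0.39. These values argue against a fall of like amount in cycling cells, but a smaller one stays open, and labelling time differs. A difference in labelling or preparation between the arms cannot be told apart from 4HT, because no label gives a batch and the library names run through all ethanol libraries before all 4HT libraries; the shares of the arms did not overlap, with a gap of 0.041 percentage points.

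The third pattern is the call of 6566 genes with small changes in synchronized cells. Among 100 splits of the 24 libraries into 12 and 12, 1, the real one, called as many. The highest of the others called 5212 and their median was 0, so the real division ranked first of 100. The splits treat all libraries as interchangeable, yet same-numbered libraries correlated up to 0.72, so they do not exclude chance division. Of the 4 others that put 9 of the 12 4HT libraries on the same side 3 called genes and 1 called 0, and every other one called 0. Gene length alone is not the whole cause, since 4342 genes were called with the trend removed. The share of Gm26917 and Gm42418 stays open: 7500 genes were called when libraries were scaled without them, but that scaling moved the median of all genes by -0.16, so the count decides nothing. A difference in preparation between the arms, as above, was not tested and may contribute to these 4342 genes.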

How the results depend on the processing

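Gene-length removal, scaling outside Gm26917 and Gm42418, omission of release 3 h and the crossed block were chosen after seeing the data; the other settings were planned. The planned scaling to added RNA was not run, since the tables hold no such counts. Counts kept within 1.5 times are not listed; 22 of 23 did so with RLE factors, 11 with DESeq2, 10 with total counts, 8 without a filter, 10 with total counts outside Gm26917 and Gm42418 and 10 with the length trend removed. Of the named genes' results past the threshold 5166 stayed past it under other settings, 719 did not and 6 reversed; with a library left out 3766 stayed and 914 did not. For list results these numbers were 765, 235 and 2, and 807, 114 and 3. When a library is left out the lone sample of its group is assumed to vary like the other groups. Where no cause is named, the cause was not tested.

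DESeq2 called 7 genes at FOXD3 14 h, 168 at 24 h, 299 for FOXD3 time, 90 for OCT4 time, 604, 1204, 526, 1587, 158 and 947 at release 0 to 5 h, and shared calls of 50 (FOXD3 and OCT4) and 97 (cycling and synchronized); in simulated FOXD3 data its false calls were 11.6% at 24 h and 15.3% at 32 h. Of its calls 1036 were higher at release 1 h, 94 at 4 h and 722 at 5 h. RLE factors gave 123 at release 0 h; at 5 h 291 of 410 were higher. Total counts gave 224 for FOXD3 time, 50 for OCT4 time, 5, 17, 55, 30, 17 and 42 at release 0 to 5 h, 1764 and 1736 for the ethanol course and its first hour, 1290 and 341 for the 4HT arm, and 32 shared by cycling and synchronized cells. Of these 3, 8, 5 and 10 were higher at release 0, 1, 2 and 3 h, and 25 at 5 h. Without a filter the counts were 15, 285 and 600 for FOXD3 14 h, 24 h and time, 457 for OCT4 time, 1704, 1039, 502, 2498, 601 and 1100 at release 0 to 5 h, 1738 for differences between release times, 5952 and 4409 for the ethanol and 4HT courses, and 118 and 148 shared. Many added genes have few counts.

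Total counts outside Gm26917 and Gm42418 gave 0, 45, 1094 and 53 for FOXD3 8, 24 and 32 h and time, 22, 61, 55, 1322, 25 and 102 at release 0 to 5 h, 536 for 4HT 1 h against 0 h, and 17 and 29 shared. Higher were 21, 21, 258, 15 and 32 at release 1 to 5 h, 152 for 4HT 1 h and 2288 of 3061 for ethanol 1 h. With the length trend removed the counts were 6, 377 and 398 for FOXD3 14 h, 24 h and time, 5337 and 600 for OCT4 16 h and time, 5126 for FOXD3 against OCT4, 96, 93, 240 and 127 at release 1, 2, 3 and 5 h, 4342 over all release times, and 181 and 201 shared. Higher were 57 of 74 at release 0 h, 50 at 2 h, 96 at 3 h, 43 of 71 at 4 h and 80 at 5 h. Fits of only the compared groups gave 69, 271 and 201 for FOXD3 8, 24 and 32 h, 6574 and 4258 for OCT4 16 and 24 h, 0, 6, 77, 0, 0 and 58 at release 0 to 5 h, 753 and 5370 for the ethanol and 4HT courses and 419 for 4HT 1 h; with 2 libraries per group these estimate the spread from few samples. Without release 3 h 5340 genes were called over all times, and 6546 as the mean of the 6 contrasts.

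Replicate numbers were not taken to pair the samples, since 2 of 4 (FOXD3), 1 of 2 (OCT4) and 4 of 6 (synchronized) treated and control pairs of a time correlated over 0.1, not all. Deviations of same-numbered treated and control samples of a time correlated from -0.25 to 0.42 (FOXD3), -0.25 to 0.74 (OCT4) and 0.01 to 0.46 (synchronized). Across times and arms they ran from -0.73 (4HT 14 h, ethanol 32 h) to 0.62 (4HT 24 h, ethanol 32 h) in cycling FOXD3-iKO cells. After release they reached 0.72 within the ethanol series and 0.67 between ethanol 4 h and 4HT 0 h. Shared preparation by number therefore stays open in the synchronized experiment. With a replicate block the counts were 0, 1, 4 and 0 for FOXD3 8, 14 and 24 h and time, 5889 and 1995 for OCT4 16 h and time, 8019 for FOXD3 against OCT4, 24, 79, 70, 1809, 51 and 139 at release 0 to 5 h, 6348, 5269 and 4210 for the ethanol course, its first hour and the 4HT course, and 3 and 4 shared. Crossed pairing in the block gave 1992 at FOXD3 32 h and 7517 at OCT4 16 h.

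Leaving out each library gave 0 to 0, 0 to 1, 2 to 17 and 572 to 4494 genes for FOXD3 8, 14, 24 and 32 h and 11 to 774 for time; 1332 to 1429, 3977 to 7807 and 0 to 151 for OCT4 16 h, 24 h and time; 1436 to 4870 for FOXD3 against OCT4; 5 to 26, 13 to 348, 18 to 48, 21 to 3710, 16 to 112 and 43 to 102 at release 0 to 5 h. It gave 1320 to 7649 and 702 to 1800 for the ethanol course and its first hour, 1172 to 2307 and 260 to 731 for the 4HT arm, 5759 to 7230 over all release times, and 1 to 31 and 2 to 54 shared. These ranges leave out libraries of the compared groups.

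Few directions reversed. With the length trend removed mt-Nd6 was 0.18 and mitochondrially encoded transcripts 0.19 at OCT4 24 h, and chromatin remodelling was -0.08 at release 3 h. In synchronized cells Rad50 was -0.05 with total counts and 0.00 outside Gm26917 and Gm42418, and Brca1 -0.06, -0.01 and, with the length trend removed, -0.02. With a library left out the medians ranged from -0.73 to 0.07 for histones at FOXD3 14 h, from -0.14 to 0.04 for ribosomal proteins at 24 h and from -0.70 to 0.10 for histones at release 0 h.

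For lists fry kept 0 of 5 camera calls at FOXD3 8 h, 0 of 5 at 14 h, 2 of 10 at 24 h and 14 of 14 at 32 h. It kept 7 of 10, 16 of 17 and 5 of 16 for OCT4 16 h, 24 h and time, and 13 of 18 for FOXD3 against OCT4. It kept 11 of 14, 1 of 5, 0 of 5, 1 of 7, 0 of 10 and 4 of 8 at release 0 to 5 h, 6 of 6 over all release times, and 10 of 10 and 6 of 7 for the first hour of the ethanol and 4HT arms.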

Other observations

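The comparisons here were chosen after the results were seen. 5 genes separated every 4HT library from every ethanol library of FOXD3-iKO cells, across 8 against 8 cycling and 12 against 12 synchronized libraries, compared in CPM of total counts, without TMM scaling, within each table: Tfap2c, Gm36287 and Gm26517 were higher, and Foxd3 and Pla2g1b lower. If all libraries were independent, chance orders would give 1.57e-06 genes per direction among the 54752 listed. The labels do not say that they are, a difference in preparation between the synchronized arms was not tested, and Foxd3 is the targeted gene. Scaling to counts outside Gm26917 and Gm42418 gave the same numbers, 3 and 2. Gm26517 (chromosome 12, 51888015 to 51889459, plus strand) had 0 counts in each of the 8 cycling ethanol libraries and 7 to 34 in the 4HT libraries, at least 46.7-fold higher against a floor of 3 counts over the ethanol group. In synchronized cells it had 0 to 1 counts with ethanol and 4 to 18 with 4HT, and in OCT4-tetOff cells 0 to 1. It lies inside Heatr5a, annotated on the minus strand, and the strand setting of the counts is not given. Gm36287 (chromosome 12, 25150915 to 25209377, plus strand) rose from a mean of 0.332 to 1.29 CPM in cycling and from 1.57 to 6.84 CPM in synchronized cells. Gm36287 overlaps Gm47705, also annotated on the plus strand. On the same chromosome Id2, at 25093799 to 25097140 (1.69 ± 0.14 at 24 h, edgeR adjusted p = 0.00019), was called at 8, 14, 24 and 32 h. Tfap2c averaged 40.5 CPM with ethanol and 58.0 with 4HT in cycling cells, and 12.8 and 25.9 in synchronized cells. Its separation was narrow. The highest ethanol and lowest 4HT libraries lay at 48.5 and 49.6 CPM in cycling cells and at 19.5 and 20.3 CPM in synchronized cells.

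Ethanol-treated cells differed between the synchronized and the cycling experiment. List members here are the genes that passed the low-count filter of the synchronized table, so members low in those libraries were left out. This tilts the counts and medians below toward higher in synchronized cells. Fewer two-cell-like genes and more primitive endoderm genes passed that filter in the cycling FOXD3-iKO table. All 15 measured two-cell-like genes were called higher in synchronized cells, with a median difference of 3.40 on the log2 scale (limma camera adjusted p = 2.1e-08, and 0.026 with an estimated correlation), and at 0 h of release it was 3.13 with 14 of 15 called. Of 22 cholesterol synthesis genes 21 were lower and none higher (median -0.95; camera adjusted p = 1.6e-10, and 0.042 with an estimated correlation), and of 13 primitive endoderm genes 9 were higher and 2 lower (median 0.98; camera adjusted p = 0.0028, and 0.042 with an estimated correlation). At 0 h of release genes of G2 and mitosis were 0.81 below cycling cells in median (35 of 39 lower; camera adjusted p = 4.4e-11, and 0.018 with an estimated correlation). The experiments also differ in labelling time, plate format and library series, so none of these differences can be assigned to the block alone. Many two-cell-like genes are in multi-copy families with uncertain counts.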
